A study of Rattus norvegicus with 352 samples.

How the data were processed

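RNA was measured in frozen whole brain hemispheres of naive, untreated heterogeneous stock rats. Per the labels' protocols, RNA was extracted with TRIzol after mechanical homogenisation, polyA RNA was enriched and libraries were made with a directional NEBNext kit. Reads were quantified with kallisto, per the submitters' processing notes; its version and settings are not given in the sources used here. The deposited table holds log2 values, which turn back into estimated counts per gene as 2 to the power of the value, minus 1. These estimated counts are not scaled for depth in the deposited table: they sum to between 5418230 and 42980793 per library, which sets the precision of low genes. Of the turned-back values between 0.5 and 5, 63.2% are whole within 0.002. The labels name 352 samples; 342 libraries are in the table, 10 are not analysed here, and every column of the table matched a sample. The labels also say that 14 libraries were renamed to correct a mix-up. All samples form a single group of n = 342, to which every mean ± SD over all libraries refers, and the blocks tested hold 335 of them. Shares of libraries are percentages of these 342. Samples are named brain with a number given in accession order.

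The table names 38354 genes, of which 38278 matched a RefSeq gene table on the assembly GRCr8 by symbol, each with its start site at an end of that gene, so coordinates come from there. Mitochondrial genes are not analysed here. Libraries were compared before use: the correlation between pairs of libraries had a median of 0.991 and a highest value of 0.995, and counts of the closest pair differed by a chi-square of 4.40 per degree of freedom, so no library was counted as a repeat of another. A level of 1 is 1 CPM, which rests on few counts in the smallest libraries.

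Each library was scaled to CPM, and log2 of the value plus a pseudocount of 1 was taken. Genes with a mean level of at least 1 were tested. Spread was the SD between libraries over the SD that a lowess trend gives at the same mean level, and an excess was 2 times the trend or more, with 95% intervals for named genes from 2000 bootstrap draws of libraries. A fold between percentiles is 2 to the power of the difference of levels at the 5th and 95th percentiles, which understates the fold of low genes. For each of 36 gene lists fixed before the data were examined, the median spread of the members was ranked among 10000 random lists of the same size drawn from 20 bins of level, and the mean pairwise Pearson r among 1000; a list stood apart at percentile 97.5 or more, or 2.5 or less. List scores are the mean z value of members. Correlations of list scores used two-sided permutation tests with 100000 permutations for Pearson's r and Spearman's rho, Benjamini-Hochberg adjustment over the family, a repeat without 2 libraries, and values within identifier blocks of at least 8 libraries, or at least 6 within a level. Where a score fell into separate levels, r was computed within each level, which departs from the single pooled test first planned for those pairs.

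Separate levels came from Gaussian mixtures of 1 to 3 components with a common SD: the Bayesian information criterion had to drop by more than 10, neighbouring means had to lie at least 4 SD apart, and each level had to hold at least 5% of the libraries. Neighbouring genes were compared after the first 10 principal components were removed, with 1000 permutations of gene positions. Identifier blocks are libraries whose identifier starts with the same 6 characters; limma's moderated F-test with a mean-variance trend compared the blocks of at least 8 libraries as a check for a batch, with adjusted p under 0.05 as the threshold. Covariates added to that model in turn were the ribosomal RNA share with Meg3 and Miat, the library total, the cell type scores, and the activity and stress scores, each also permuted 20 times. The 100 assignments of libraries to blocks, the real one included, were fitted without covariates and with each set. Tph1 was compared with 11 other pineal genes within its levels, without the level minimum, and parents of gene copies were reassigned 1000 times.

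Genes are named by a rule fixed before the data were examined: the 10 of highest mean level; the 25 of largest SD over trend with a mean of at least 3 and a name other than a bare locus identifier; up to 4 members of each list by SD over trend; the 15 autosomal genes of separate levels with the largest gain in fit and such a name; the 10 of largest F between blocks; the 10 neighbouring pairs of largest absolute r; and Y-linked list members. Other named genes are said to be chosen after their values were seen. Of the 10 genes of highest mean level, 3 are not reported here.

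Alternatives fixed beforehand were a pseudocount of 0.1, median ratio scaling, the values as deposited, a level minimum of 3 or none beyond a value above 0 in 20% of libraries, removal of block means, exclusion of the 5% of libraries with fewest genes, 3 times the trend, a separation of 3 SD, 10 components removed before the search for levels, 0 or 20 components removed for neighbours, pairs up to 1 Mb, Spearman's rho, scores adjusted for neurons, astrocytes and oligodendrocytes, and a Kruskal-Wallis test. Exclusion of the renamed libraries, and of 7 libraries with a list score more than 1 unit beyond that of the next library, were chosen after seeing the data.

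The steps for spread of single genes, separate levels, neighbouring genes and blocks were tested on simulated data. Of genes given 2.5 or 4 times the trend 100% were called, and of those at 1.5 times and of 16483 unchanged genes 0%. These genes had normal values with exactly the SD given, so the outcome checks the calculation only. It does not show how far real genes scatter around the trend. Levels 5 or 6 SD apart were found in 100% of simulated genes, levels 3 SD apart in 0%, and none in 3000 genes of each single-level shape. Neighbours that shared 20% of variance gave a median r of 0.198, and independent ones −0.00137. A shift of 1 SD between blocks was called in 100% of genes, one of 0.5 SD in 19%, and 0.0303% of 16483 unshifted genes were called. Genes were drawn independently there. Random assignments of the real libraries, whose genes vary together, called up to 513 genes, so 0.0303% need not be the rate of false calls in these data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.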

Results

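Gene expression was measured by polyA RNA sequencing in whole brain hemispheres of naive heterogeneous stock rats, an outbred population descended from several inbred strains and used to map the genetic basis of traits. The labels name a single group, untreated brain, and state that the cohort serves statistical genetics, so the design implies no contrast between treatments. It asks instead how far each gene differs between rats, which genes move together, and which genes fall into separate levels of the kind a segregating variant of large effect would give. The table held 97.2% of the samples named in the labels, with 10 samples not analysed here, and estimated counts for 38354 genes. Library totals ranged from 5418230 to 42980793 estimated counts (median 21881769). Between 22962 and 27876 genes were above 0 in a library (median 26366). Each library is taken here as 1 rat, which the labels do not spell out. P-values measure the spread between these libraries, except that for the median r of neighbouring genes, which comes from permuted gene positions. Levels are given as log2(CPM + 1), where CPM is the estimated count scaled by the library total, not corrected for transcript length, with mean ± SD over all libraries. Coordinates are on GRCr8.

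The highest levels in these hemispheres included those of genes of myelin, synapses and astrocytes. Myelin basic protein, Mbp (chromosome 18, 78130652 to 78241174), had the highest mean level of all genes, 12.43 ± 0.11. The fatty acid desaturase gene Scd2 stood at 11.53 ± 0.11 and the astrocytic glutamate transporter gene Slc1a2 at 11.42 ± 0.11. The presynaptic gene Snap25 (11.24 ± 0.05), Zwint (11.07 ± 0.06) and the astrocytic matrix gene Sparcl1 (11.01 ± 0.14) were also among the 10 highest. So was the ribosomal RNA gene LOC120093067, at 11.11 ± 0.41, the widest spread of the 10. The 10 genes of highest mean level took 2.89% of the counts of an average library. A mean level of at least 1 was reached by 16683 genes, of which 14690 were protein coding and 1922 long noncoding, and 11740 genes reached 3. Ribosomal RNA genes together took between 0.220% and 1.39% of a library (median 0.526%).

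Sex-linked genes, haemoglobin genes, activity-regulated genes, a glucocorticoid-induced gene and several gene copies were among the 25 named genes of largest spread between rats. Spread was set against a smooth trend of SD on mean level, and 871 of the 16683 genes had an SD of at least 2 times the trend. Xist, the noncoding RNA of the inactive X chromosome, had an SD of 4.52 (95% bootstrap interval 4.46 to 4.55), 42.9 times the trend, and the Y-linked helicase gene Ddx3y an SD of 3.08 (17.3 times). Among haemoglobin genes, the beta globin gene Hbbl1 had an SD of 2.42 at a mean level of 4.19 (18.9 times the trend), Hbb 0.69 at 6.78, Hba-a1 0.50 at 7.84 and Hba-a2 0.49 at 6.44. Among activity-regulated genes, Arc had an SD of 0.70 (0.64 to 0.75) at a mean of 6.96, and its level at the 95th percentile of rats was 5.09 times that at the 5th percentile. Fos spread 4.94-fold and Nr4a1 3.89-fold over the same percentiles. The glucocorticoid-induced kinase gene Sgk1 spread 3.45-fold (SD 0.55, 0.52 to 0.59).

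Further genes of this set included single genes, gene copies and noncoding RNA. Fam107a (chromosome 15, 19038726 to 19060644), an actin-associated stress response gene, ranged 6.41-fold between the 5th and 95th percentiles around a mean of 8.37. Zfp532 on chromosome 18 ranged 4.13-fold, and the macrophage pore-forming protein gene Mpeg1 on chromosome 1 (218876848 to 218881364) ranged 8.60-fold. The class I histocompatibility gene RT1-CE16 on chromosome 20 (3261656 to 3265548) ranged 35.4-fold. Ndrg3-ps1 (chromosome 3, 165890090 to 165925107) ranged 14.8-fold, Zfp94l1 11.6-fold, Eef1a1l1 7.28-fold, Spetex2l2 6.26-fold, Hsp90aa1-ps17 4.0-fold, Rpl30 2.78-fold and Tpt1l3 2.48-fold. Several of these names mark a pseudogene or a gene like another one, and how the counting divided reads between such copies is not given in the sources used here, so their levels are uncertain, as are those of the haemoglobin and RT1 families. The ribosomal RNA genes Rn18s and Rn28s spread 8.19-fold and 2.43-fold, and the nuclear noncoding RNA Meg3 2.60-fold. Ilrun, an inhibitor of inflammatory signalling, rested on few animals: 2 libraries lay under a level of 3, the lowest at 1.20, against a median of 8.34. Xist, Ddx3y, Hbbl1, Fam107a, RT1-CE16, Ndrg3-ps1, Zfp94l1, Eef1a1l1, Spetex2l2 and Rpl30 fell into separate levels, so their SD and fold span levels and not a continuous range. Fam107a was at 6.92 ± 0.26 in 73 libraries and 8.77 ± 0.43 in the others, and Hbbl1 at 0.31 ± 0.47 in 78 libraries, 3.04 ± 0.70 in 54 and 5.92 ± 0.63 in the others. The 25 genes named here, from Xist to Meg3 at 5.86 times the trend, had the largest SD over trend among genes with a mean level of at least 3 and a name other than a bare locus identifier.

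**Figure D1:**
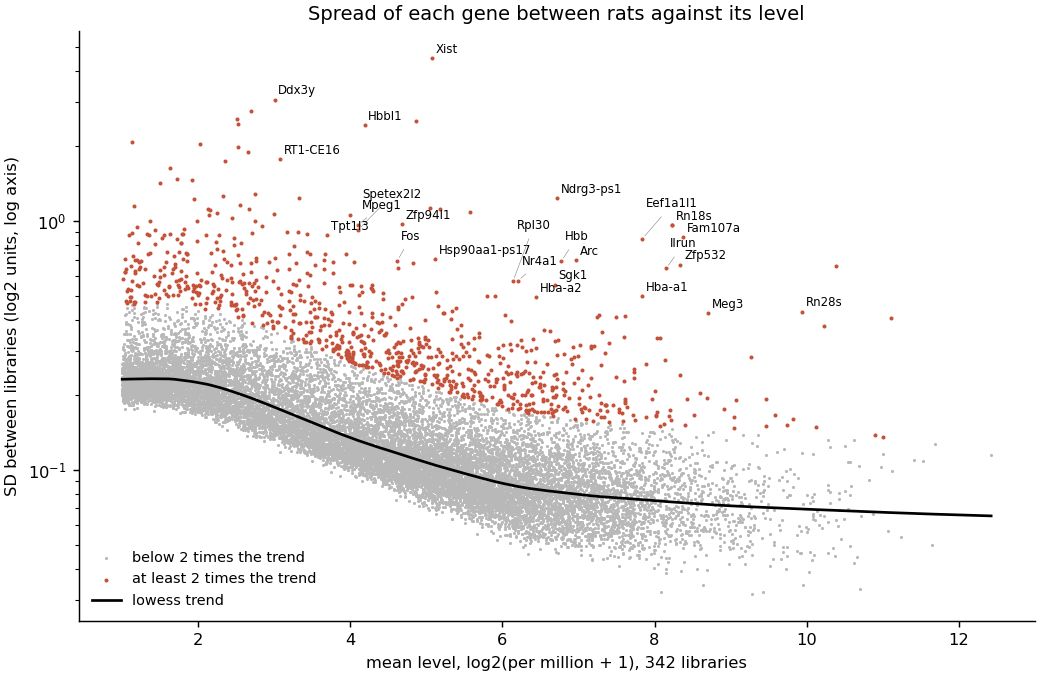
SD between libraries (log2 units, log axis) against mean level for each of the 16683 genes with a mean of at least 1, over all libraries. The line is the lowess trend, red points are the 871 genes at 2 times the trend or more, and the 25 named genes are labelled, from Xist at 42.9 times the trend to Meg3 at 5.86 times.

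Of 36 gene lists fixed before the data were examined, 34 had enough members to test, and 26 of them spread more between rats than random lists of the same size and level. Lists of unrelated genes would give 0.85 per side. Members of most lists moved together and all lists rest on the same libraries, so the percentiles describe these libraries and do not test chance. None spread less. The immediate early genes, transcribed within minutes of neuronal firing, had the highest spread of any list not tied to sex: all 12 members exceeded 2 times the trend, the median member had 5.05 times the trend, and the members moved together with a mean pairwise r of 0.79. Arc, Nr4a1, Fos and Junb led the list (Junb 5.91 ± 0.50). Glucocorticoid-responsive genes stood at 2.82 times the trend with 11 of 12 members over 2 times. They were led by Sgk1, the transcription factor gene Zbtb16 (6.55 ± 0.36), Per1 and the pyruvate dehydrogenase kinase gene Pdk4 (2.88 ± 0.60). Heat shock and chaperone genes stood at 2.0 times with 6 of 12 over 2 times; the inducible Hspa1b and Hspa1a ranged 4.53-fold and 4.20-fold between the 5th and 95th percentiles, the endoplasmic reticulum chaperone gene Hspa5 1.67-fold and the small heat shock gene Hspb1 2.19-fold.

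Circadian genes also spread widely. The labels do not state the time of day at which tissue was taken. The clock genes of the Dbp phase had 7 of 12 members over 2 times the trend and a list median of 2.52 times, with a mean pairwise r of 0.52. Dbp itself stood at 7.31 ± 0.36 and ranged 2.38-fold over 2 separate levels (6.60 ± 0.21 in 50 libraries and 7.44 ± 0.20 in the others), Per1 2.11-fold, Nr1d1 1.95-fold and Per2 2.0-fold. The smaller list of the opposite phase had a median of 1.80 times with none of its 6 members over 2 times; Cry1 stood at 4.59 ± 0.22, Nfil3 at 3.60 ± 0.28, Npas2 at 5.91 ± 0.16 and Bmal1 at 4.94 ± 0.19.

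Markers of cerebellum, hypothalamus, monoamine nuclei, choroid plexus and meninges spread more than random lists. Cerebellar genes had 9 of 12 members over 2 times the trend and a list median of 3.17 times, led by the granule cell genes Gabra6 (7.25 ± 0.41), Cbln3 (6.11 ± 0.40) and Neurod1 (6.94 ± 0.29) and by Eomes (3.33 ± 0.58). A single library, brain 4, held part of that spread: without it the list median was 2.52 times the trend, and Gabra6 moved from 5.25 to 3.01 times, Cbln3 from 4.57 to 3.01 and the Purkinje cell gene Pcp2, named here for this movement after its values were seen, from 3.52 to 2.22. Hypothalamic neuropeptide genes stood at 2.44 times the trend with 6 of 10 members over 2 times; the oxytocin gene Oxt ranged 2.67-fold, the melanin-concentrating hormone gene Pmch 1.89-fold, the vasopressin gene Avp 2.35-fold and the thyrotropin-releasing hormone gene Trh 2.51-fold. Monoamine neuron genes stood at 1.75 times the trend, with the serotonergic genes Tph2 (2.74 ± 1.0, 7.46-fold range) and Slc6a4 (1.98 ± 1.0, 7.70-fold) far ahead of Ddc (2.26-fold) and Th (1.91-fold). Choroid plexus genes, 6 of 12 over 2 times and a median of 2.02 times, were led by the transthyretin gene Ttr (9.26 ± 0.28), Enpp2 (8.60 ± 0.20), Clic6 and Kl. Meningeal and perivascular fibroblast genes (6 of 12, 1.94 times) were led by Igf2 (6.90 ± 0.28), Col1a2, Col1a1 and Col3a1. The pituitary and pineal list had 4 measured members, a median of 3.07 times the trend, and Tph1, the melatonin pathway hydroxylase gene, at 2.52 ± 1.99 over 2 separate levels. Its other members were Cga (1.09 ± 0.88), Pomc (1.82 ± 0.57) and Asmt (2.05 ± 0.30).

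Most lists of the main cell types also spread more than random lists. Oligodendrocyte genes stood at 1.86 times the trend, with Opalin at 6.68 ± 0.24, Mobp at 10.90 ± 0.14, Cnp at 9.17 ± 0.14 and Mal at 8.10 ± 0.14. Astrocyte genes stood at 1.66 times (Gfap 9.08 ± 0.19, Sox9 4.62 ± 0.24), endothelial and pericyte genes at 1.62 times (Rgs5 4.42 ± 0.23, Cldn5 5.87 ± 0.17), oligodendrocyte precursors at 1.49 times (Olig2 5.44 ± 0.19) and microglia at 1.41 times (Tmem119 4.15 ± 0.26, P2ry12 3.73 ± 0.28). Striatal projection neurons (1.33 times, led by Pde10a at 7.58 ± 0.16), thalamic and habenular neurons (1.33 times, led by Calb2 at 6.83 ± 0.25), cortical and hippocampal excitatory neurons (1.33 times, led by Nrgn at 9.71 ± 0.12) and inhibitory neurons (1.30 times, led by Reln at 7.54 ± 0.17) passed by smaller margins, the last at percentile 98.1. General neuronal genes did not pass, at 0.93 times the trend and percentile 20.7, although the neurofilament gene Nefm alone spread 2.43 times the trend. The olfactory bulb and neuroblast list (1.0 times, led by Cdhr1 at 3.73 ± 0.35) and ependymal genes (1.20 times, led by Spag6l at 2.60 ± 0.39) did not pass either.

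Haemoglobin genes led the spread of the red blood cell list. The red blood cell list had 7 of 9 members over 2 times the trend and a median of 3.93 times, with Hbb, Hba-a1, Hba-a2 and Hbb-bs (4.30 ± 0.52) ahead of its other members. Of the leukocyte list, Ptprc alone reached a mean level of 1 (1.99 ± 0.21), too few members for a test. Interferon-stimulated genes had a list median of 1.58 times the trend with Mx2 (4.43 ± 0.49) and Irf7 (2.36 ± 0.53) in front of Ifit3 and Usp18. MHC class II genes stood at 1.69 times, led by Cd74 (3.74 ± 0.43). MHC class I and antigen presentation genes did not pass (1.15 times, percentile 91.7; percentile 98.9 with a level minimum of 3 and 98.4 with none), with RT1-A2 at 2.79 ± 0.54 and B2m at 7.45 ± 0.13.

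Of 5 metabolic and housekeeping lists, cholesterol synthesis alone spread more than random lists. These genes stood at 1.35 times the trend, led by the lanosterol synthase gene Lss (5.91 ± 0.22). Nuclear-encoded oxidative phosphorylation genes (1.09 times), cytosolic ribosomal protein genes (1.14 times), glutathione S-transferase and detoxification genes (1.10 times) and reference genes (0.95 times) lay within the range of random lists. Ribosomal protein genes such as Rpl32 (7.06 ± 0.11) and Rps23 (7.32 ± 0.10) nonetheless had a mean pairwise r of 0.66, and oxidative phosphorylation genes such as Ndufa2 (4.90 ± 0.18) and Cox7c (6.71 ± 0.12) 0.48. Among detoxification genes Sult1a1 (4.14 ± 0.33) spread the most, and among reference genes Actb (9.68 ± 0.09). In all, 31 of the 34 lists had a mean pairwise r that at most 2.5% of random lists exceeded. The exceptions were general neurons (0.10), olfactory bulb (0.10) and inhibitory neurons (−0.03). Of the 31, the Bmal1 phase list was no longer past the threshold with a pseudocount of 0.1 (r = 0.134), without the 5% of libraries with fewest genes (0.135) and without the libraries that stand apart (0.131, chosen after seeing the data), detoxification genes with no level minimum (0.0762) and thalamic neurons with a minimum of 3 (0.0816). The olfactory bulb list passed under median ratio scaling (0.0902), with either other level minimum (0.173 at 3, 0.130 with none) and without the 5% of libraries (0.104). The mitochondrial-encoded list was not tested because none of its genes was in the table.

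**Figure D2:**
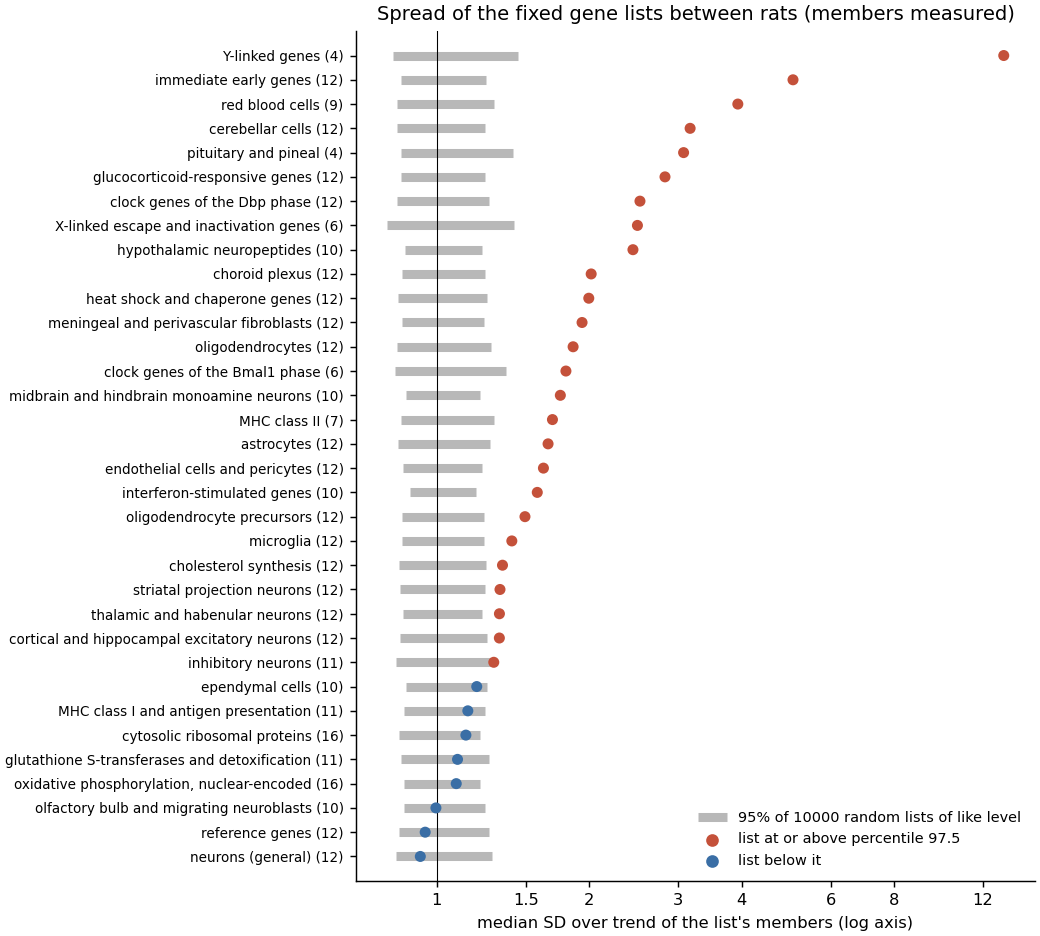
Median SD over trend (log axis) of the measured members of each of the 34 tested lists, with member counts in brackets, against the central 95% of 10000 random lists matched on level (grey bars). The 26 red points are lists that at most 2.5% of random lists exceeded, from inhibitory neurons at 1.30 to Y-linked genes at 13.2.

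Gene lists that stand for neighbouring tissues or linked programmes were compared by the mean z value of their members in each library. Of 18 pairs fixed in advance, 17 had enough members left once shared genes were removed, giving 20 tests, since the Dbp-phase score fell into separate levels and its 3 pairs were tested within each level. The strongest relation was between oxidative phosphorylation and ribosomal protein genes (r = 0.86, rho = 0.83), which ranged from 0.78 to 0.94 within the 7 identifier blocks, groups of libraries whose identifiers start alike. Both of these scores also followed the second principal component of the tested genes (r = 0.77 each). Reference genes did so too (r = 0.54), so the relation is not particular to these lists. What that component stands for was not tested. MHC class I rose with interferon-stimulated genes (r = 0.80, rho = 0.66, within blocks 0.62 to 0.98). Choroid plexus rose with ependymal genes (r = 0.71, rho = 0.72, within blocks 0.52 to 0.89) and with meningeal fibroblast genes (r = 0.52, rho = 0.51, within blocks 0.13 to 0.62). Oligodendrocytes rose with their precursors (r = 0.69, rho = 0.65, within blocks 0.57 to 0.97) and striatal with cortical neurons (r = 0.66, rho = 0.65, within blocks 0.36 to 0.72). Cerebellar genes fell as cortical and hippocampal genes rose (r = −0.53, rho = −0.52, within blocks −0.77 to −0.31), the only negative relation among the pooled pairs past the threshold. Each of these 7 relations had a two-sided permutation p of 1e-05 for r and for rho, the smallest that 100000 permutations can give (Benjamini-Hochberg adjusted 1.43e-05 over the 20 tests), and without the 2 libraries farthest from the median of the first score r was 0.86, 0.72, 0.70, 0.53, 0.66, 0.65 and −0.54 in the order given.

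Scores of activity and stress genes were related to each other more loosely. Immediate early genes rose with heat shock genes (r = 0.42, rho = 0.39, 0.41 without 2 libraries, within blocks −0.08 to 0.78) and with glucocorticoid-responsive genes (r = 0.26, rho = 0.24, 0.26 without 2 libraries, within blocks 0.02 to 0.62), each at the same smallest permutation p of 1e-05 for r and rho. General neuronal genes rose with astrocyte genes (r = 0.50, rho = 0.50, 0.51 without 2 libraries, within blocks 0.24 to 0.56) and oligodendrocyte genes (r = 0.39, rho = 0.37, 0.39 without 2, within blocks 0.17 to 0.70), and hypothalamic with pituitary and pineal genes (r = 0.37, rho = 0.39, 0.37 without 2, within blocks −0.11 to 0.52), also at a permutation p of 1e-05. General neuronal, astrocyte and oligodendrocyte scores all moved with the first principal component of the tested genes (r = 0.74, 0.71 and 0.55). Choroid plexus (0.64), ependymal (0.61), meningeal fibroblast (0.60) and reference genes (0.60) moved with it in the same direction. So did oligodendrocyte precursor (0.58), hypothalamic (0.57), pituitary and pineal (0.48) and cerebellar genes (0.38). Cortical and hippocampal (−0.56) and striatal genes (−0.52) moved against it. The relations among these scores may thus not be particular to each pair, and what the component stands for was not tested. Microglia and interferon-stimulated genes were related at r = 0.29 (permutation p = 3e-05, adjusted 4e-05) and rho = 0.13 (p = 0.0129, adjusted 0.0161), within blocks 0.02 to 0.85; r was 0.14 without 2 libraries and 0.15 (permutation p = 0.00559) without 1 library of block G, which had the highest score in both lists. The size of r rested on that library. Red blood cell and endothelial genes were not past the threshold (r = 0.0967, permutation p = 0.0729, adjusted 0.0810), with rho = 0.12 (p = 0.0239, adjusted 0.0281), r = 0.12 without 2 libraries and −0.29 to 0.40 within blocks. Without 1 library of block D their r was 0.12 (unadjusted permutation p = 0.0270). A test of whether r differed between blocks passed for none of the 20 relations (lowest unadjusted permutation p = 0.149, every adjusted p = 0.889).

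Within the lower level of the Dbp-phase score (54 libraries), the score fell as the opposite clock phase rose (r = −0.63, rho = −0.61, permutation p = 1e-05 for each, −0.62 without 2 libraries, within 3 blocks −0.66 to −0.50). Within the upper level (84.2% of libraries) r was −0.20 (permutation p = 7.6e-04, adjusted 9.5e-04) and rho −0.13 (p = 0.0272, adjusted 0.0303), with −0.17 without 2 libraries and −0.77 to −0.08 within blocks. Immediate early genes rose with the Dbp-phase score within its upper level (r = 0.33, rho = 0.36, permutation p = 1e-05 for each, 0.35 without 2 libraries, within blocks −0.22 to 0.55) and gave r = 0.08 within the lower level (permutation p = 0.556, adjusted 0.556, rho = 0.12, p = 0.373, r = 0.20 without 2 libraries, within 3 blocks −0.22 to 0.48). With Per1 left out of both lists, glucocorticoid-responsive genes gave r = 0.15 in the upper level (permutation p = 0.00939, adjusted 0.0110, rho = 0.17, p = 0.00302, 0.17 without 2 libraries, within blocks −0.45 to 0.19) and r = −0.16 in the lower (55 libraries, permutation p = 0.259, adjusted 0.273, rho = −0.13, p = 0.364, r = −0.20 without 2 libraries, within 3 blocks −0.43 to −0.06). Values in the lower and upper levels were not compared with each other.

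**Figure D3:**
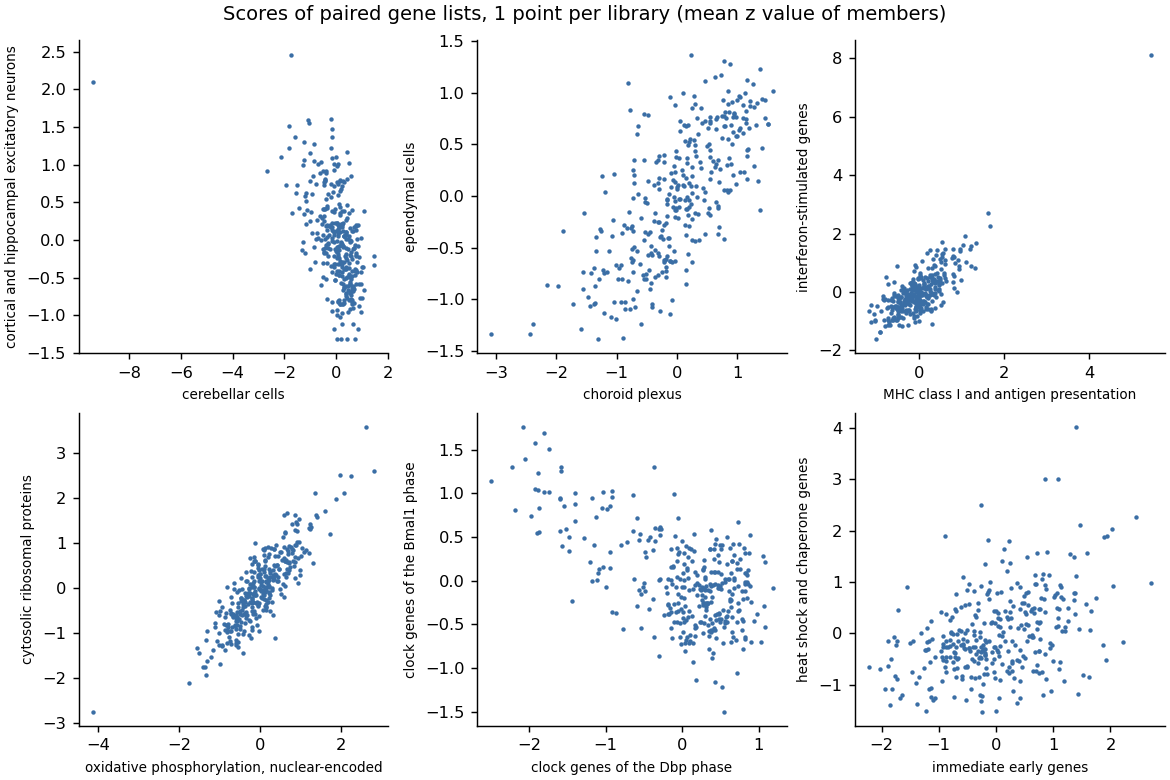
Scores of 6 pairs of gene lists, each point a library, as the mean z value of the members. Oxidative phosphorylation and ribosomal protein genes lie along a line (r = 0.86), cerebellar and cortical scores slope down with brain 4 far to the left, 1 library of block G lies apart at the upper right for MHC class I and interferon-stimulated genes, and the Dbp-phase score has a lower level of 54 libraries and an upper level of the rest.

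Separate levels, rather than a continuous spread, were found for 0.821% of the 16683 genes. The values of 78.8% of these fell into 2 levels and those of the other 29 genes into 3, at least 4 within-level SD apart. On X lay 8 of them, on Y 5 and on autosomes 90.5%, and 58 had only a locus identifier for a name. The ribosomal protein gene copy Rpl30l2 (chromosome 10, 37332379 to 37332860) was at 5.36 ± 0.14 in 66 libraries and near 0 in the others (0.12 ± 0.22). Fam111a, a protease gene of DNA replication on chromosome 1 (219065542 to 219081213), stood at 0.52 ± 0.16 and at 4.04 ± 0.27 in 43% of libraries each and at 4.99 ± 0.25 in 48 libraries. Ak1, the adenylate kinase gene on chromosome 3 (36310113 to 36320760), was well expressed at each of its levels, 6.29 ± 0.08 in 50.3% of libraries, 6.84 ± 0.05 in 36.5% and 7.25 ± 0.06 in 13.2%. Zfp94l1 had 30 libraries at 1.87 ± 0.20, 43.3% of libraries at 4.49 ± 0.11 and 48% at 5.37 ± 0.08. RT1-CE16 had levels of 0.55, 3.71 and 5.21 in 29.8%, 49.4% and 20.8% of libraries, and its neighbour RT1-CE15 was at 3.25 ± 0.18 in 56 libraries and 0.95 ± 0.25 in the others. The beta globin gene Hbb-b2 was absent or nearly so in 48.5% of libraries (0.00 ± 0.02), at 2.66 ± 0.48 in 7.60% and at 5.27 ± 0.61 in 43.9%.

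Among genes of 2 levels, the carbonic anhydrase gene Car3 stood at 3.81 ± 0.23 in 50 libraries and 1.44 ± 0.29 in the others, the centrosomal gene Ccdc77 at 3.40 ± 0.23 in 41.2% and 1.82 ± 0.18 in 58.8%, and the ribosome assembly GTPase gene Gtpbp4 at 4.47 ± 0.21 in 30.7% and 3.30 ± 0.13 in 69.3%. The heparanase-like gene Hpse2 was at 2.41 ± 0.26 in 82 libraries and 0.88 ± 0.20 in the others, Mtm1 at 6.33 ± 0.13 in 49 and 5.72 ± 0.07 in the others, and Rps10l6 at 2.89 ± 0.25 in 54 and 1.24 ± 0.21 in the others. Ppp2r5al1 had levels of 0.06, 2.12 and 2.96 in 10.5%, 45.3% and 44.2% of libraries, and Prmt1l1 of 2.31, 3.87 and 4.63 in 41.8%, 46.2% and 12%. Copies such as Rpl30l2, Rps10l6, Ppp2r5al1 and Prmt1l1 are uncertain where reads could be shared with the parent gene. The 15 genes named from Rpl30l2 to Prmt1l1 had the largest gain in fit over a single level among autosomal genes with a name other than a bare locus identifier. At a separation of 3 within-level SD, 0.832% of all genes in the table passed, against 0.357% at 4.

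**Figure D4:**
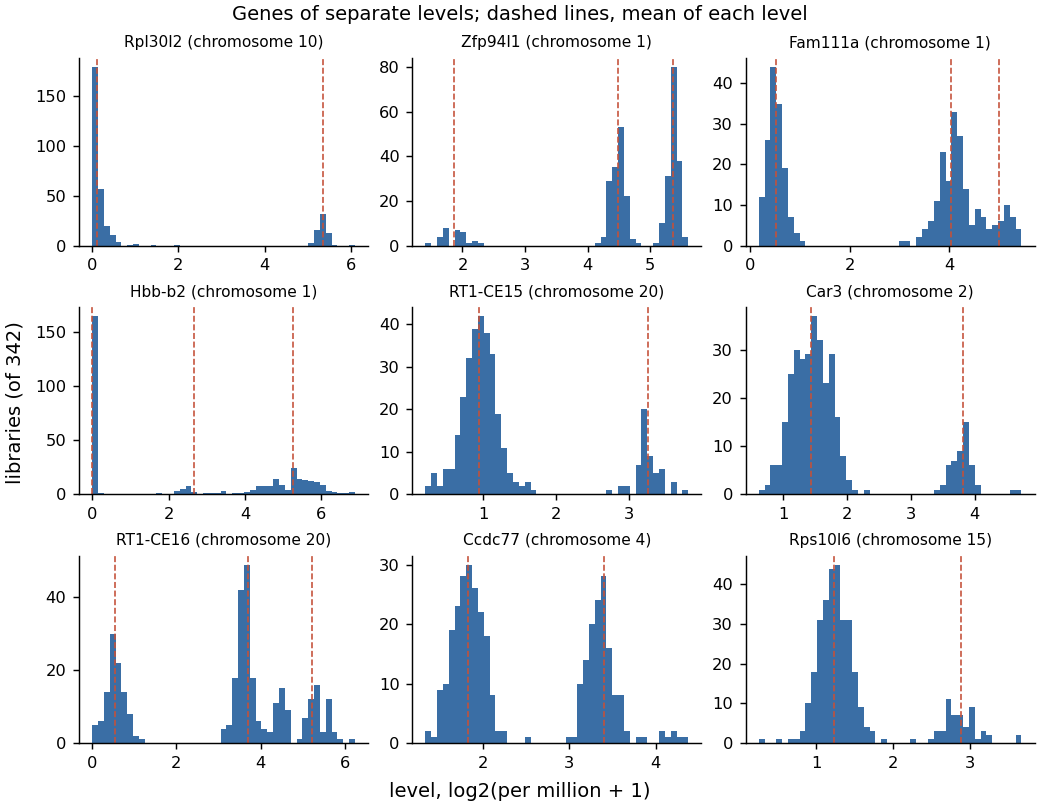
Number of libraries (y axis) at each level, log2(CPM + 1) (x axis), for 9 genes of separate levels, with dashed lines at the mean of each level. Rpl30l2 has 66 libraries at 5.36 and the others near 0, and Zfp94l1 has 8.77%, 43.3% and 48% of libraries at 1.87, 4.49 and 5.37.

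Of the 11 genes of the sex chromosomes with 2 levels, 8 assigned the libraries to the same 2 sets. Ddx3y was at 6.19 ± 0.11 in 48.2% of libraries and 0.04 ± 0.12 in the others. The other Y-linked list members past the level minimum, Eif2s3y, Kdm5d and Uty, placed every library on the same side as Ddx3y, and Xist, Eif2s3, Kdm6a and LOC134484082 placed every library on the opposite side. Of the other 3, Ddx3x departed from this division in 8 libraries and the Y-linked LOC103694537 in 7, and LOC134484057 on X had a lower level of 18 libraries that did not follow it. Single libraries lay between levels: Xist had levels of 0.42 ± 0.56 and 9.42 ± 0.22, but 1 library of block E had Xist at 4.89 with Ddx3y at 6.16, 1 of block D had Xist at 3.58 with Ddx3y at 6.32, and another of block D had Ddx3y at 1.12 with Xist at 9.22. These libraries and the 3 genes named only by a locus identifier were chosen after their values were seen. Mean levels over all libraries were 2.69 ± 2.78 for Eif2s3y, 2.52 ± 2.47 for Kdm5d, 2.02 ± 2.04 for Uty and 3.0 ± 3.08 for Ddx3y. Usp9y (0.23 ± 0.24), Uba1y (0.04 ± 0.12), Zfy1 and Sry lay under the level minimum. The X-linked list stood at 2.49 times the trend with 4 of 6 members over 2 times (Xist, Eif2s3 at 7.02 ± 0.32, Kdm6a at 5.02 ± 0.28 and Ddx3x at 8.21 ± 0.17), against 13.2 times for the Y-linked list.

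Neighbouring genes varied together slightly more than genes on different chromosomes, with a small number of strong pairs. After the first 10 principal components were removed, the median r of 28616 gene pairs with start sites within 100 kb was 0.0108, against 0.000838 for pairs on other chromosomes; permuting gene positions gave medians of at most 0.00231 in 1000 permutations (one-sided permutation p = 0.001, the smallest they can give). Pairs are across genes, which are not independent replicates. An absolute r over 0.5 was found in 1.36% of near pairs and 0.00213% of pairs on other chromosomes, and 65.6% of the 390 near pairs were positive. The share fell with distance, from 1.89% within 10 kb to 0.151% between 1000 and 5000 kb. Of the 10 pairs of largest absolute r, 4 involved genes of separate levels and have no pooled r: Uty with Ddx3y, Xist with the locus LOC134484082 beside it, and the pairs LOC134483370 with LOC134483365 on chromosome 1 and LOC134480525 with LOC134480526 on chromosome 9. Of the other 6, Cers1 and Gdf1 on chromosome 16 share the start site 19146480 and had r = 1 and rho = 1, as did the 3 pairs among Aldh3b3l-ps1, Aldh3b2-ps1 and Aldh3b2l1 on chromosome 1 and the ribosomal RNA genes Rn18s and LOC120102105 on chromosome 11. A pair with r = 1 does not give 2 separate measurements. The alpha globin genes Hba-a2 and Hba-a1, 13442 bp apart on chromosome 10, had r = 0.97 and rho = 0.96 (permutation p = 1e-05 for each, adjusted 1e-05 over 6 pairs, 0.96 without 2 libraries, within blocks 0.89 to 0.98). The pair was picked for its r in these same libraries, so this p adds nothing to the size of r. How reads were divided between the globin genes is not known.

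Besides a mark on the 14 renamed libraries, the libraries are divided by the start of the library identifier, whose meaning the labels do not give. Of its 7 larger blocks, A, B, C, E, F and G held 18, 56, 62, 33, 8 and 13 libraries and D held 42.4% of all libraries, and immediate early genes were among those that differed between them. Limma's moderated F-test called 1370 of 16683 genes at a Benjamini-Hochberg adjusted p under 0.05. The 10 genes of largest F were Apold1, a vascular immediate early gene, Ccn1, Klf4, Klf2, Atf3, Zfp36, Sik1, Tcim, Id1 and Btg2, and each had its highest mean in block A. Apold1 was at 4.76 ± 1.10 in block A, 3.82 ± 0.88 in block C and 3.17 ± 0.51 in block D (adjusted p = 6.39e-17), with 27.7% of its variance between blocks. Klf2 stood at 4.83 ± 0.65, 4.36 ± 0.52 and 3.97 ± 0.41 in the same blocks (adjusted p = 1.57e-10) and Btg2 at 4.75 ± 0.79, 4.26 ± 0.62 and 3.89 ± 0.43 (adjusted p = 2.31e-08). Differences were modest beside the spread within blocks: the median of all tested genes was 2.61% of variance between blocks, against 1.80% expected by chance, the median of the called genes, which were chosen for their F, was 6.63%, and block means differed by more than 1 log2 unit for 6 called genes. Without the 17 libraries with fewest genes detected, of which block A held 4, the count was 498, of which 482 were among the 1370, and the rank-based Kruskal-Wallis test called 717 genes.

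Of the 34 list scores, 9 differed between blocks in a permutation test. Immediate early genes had the largest share of variance between blocks, 13.6% (permutation p = 1e-05, adjusted 1.7e-04), with a mean standardised score of 0.79 ± 1.04 in block A, 0.58 ± 1.04 in block C and −0.29 ± 0.86 in block D. The olfactory bulb list followed with 13.1% (adjusted p = 1.7e-04), highest in block C (0.64 ± 1.13) and block A (0.55 ± 1.15). The choroid plexus list had 7.17% (adjusted p = 0.00555) and was lowest in block F (−1.24 ± 1.24, n = 8). Glucocorticoid-responsive genes (5.98%), microglia (5.98%), MHC class I (5.90%), heat shock genes (5.81%), reference genes (5.46%) and astrocytes (5.44%) were the other lists past the threshold, and red blood cells had the smallest share (0.830%). In block G (n = 13) the MHC class I score was 0.89 ± 2.75 and the microglia score 0.25 ± 2.02. The same library of that block had the highest score of all in both lists.

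**Figure D5:**
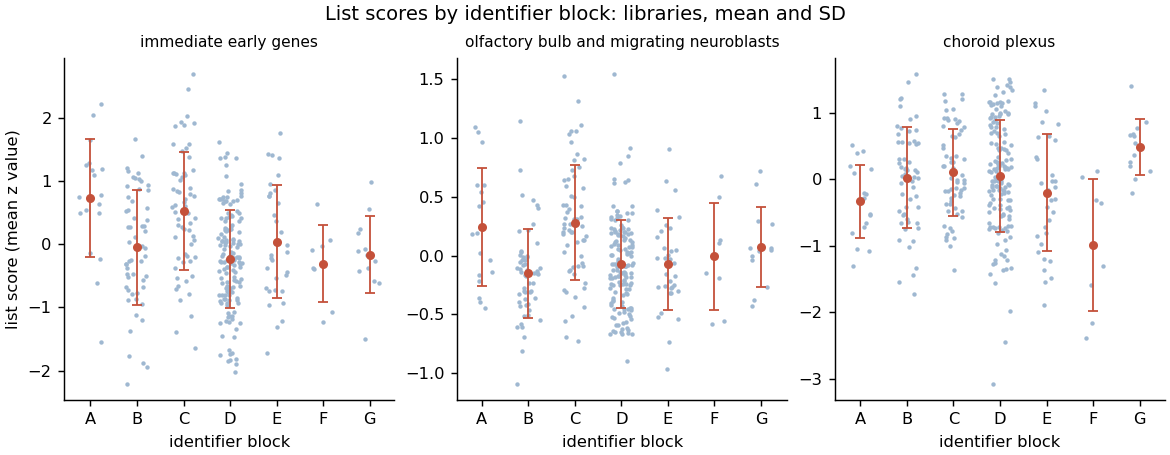
List scores (mean z value of members) of immediate early, olfactory bulb and choroid plexus genes in identifier blocks A to G, of which F is the smallest with 8 libraries; small points are libraries, and large points with bars are mean and SD. Immediate early scores are highest in blocks A and C, and the choroid plexus score is lowest in block F.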

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

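Exclusion of the renamed libraries and of the 7 libraries that stand apart were chosen after seeing the data. Of 1407 values under 18 settings, 1294 stayed on the same side of the threshold or within the bounds set, 38 were weaker, 15 stronger, 56 moved and 4 reversed. All 4 reversals came with the values as deposited, which are not scaled for depth, so that every gene rises with library total: r was 0.786 for cerebellar and cortical genes, 0.918 and 0.923 for the Dbp and Bmal1 phases in the lower and upper level, and 0.781 for the Dbp phase and glucocorticoid-responsive genes in the lower level. With those values r was also 0.708 for immediate early genes and the Dbp phase in the lower level and 0.75 for red blood cells and endothelium, excess spread was found in 0.454% of the genes in the table (2.27% with scaling), separate levels in 18% (0.357%), 5 lists shared variation (31) and 6012 genes differed between blocks (1370). By construction, 3 times the trend left 0.712% of genes and no level minimum gave 28940 expressed genes. Likewise a minimum of 3 left 0.169% of separate levels and a separation of 3 SD gave 0.832%. With no level minimum, separate levels were found in 5.72% (2194 genes). This rise from 0.357% was far larger than that of the genes tested, from 16683 to 28940. Most calls under that setting were thus in genes under the level minimum of 1, and the cause was not tested. Red blood cells and endothelium passed the threshold with r of 0.120 under median ratio scaling, 0.114 with a minimum of 3 and rho of 0.122, and the Dbp phase and glucocorticoid-responsive genes in the lower level with −0.291 without the 5% of libraries with fewest genes; the cause was not tested. Blocks differed for 498 genes without those libraries and 717 in the Kruskal-Wallis test; the cause was not tested. No paired analysis was possible because the labels give a single group.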

Other observations

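Genes in the next paragraph outside the fixed rule were chosen after their values were seen. The tests chosen only after the result was seen are Hardy-Weinberg proportions, both tests of Tph1, the ribosomal and nuclear RNA test, the activity test, the permuted covariates, the reassigned parents of copies, the random assignments without libraries of fewest genes and those with covariates in the model, the accuracy bound for renamed libraries, and the rule that a block explanation is excluded as the whole cause when more genes are called than in every random assignment with the same covariates.

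Single hemispheres stood apart in whole gene groups. Brain 4, in block A, had a cerebellar score of −9.41, with the next library at −2.67: Gabra6 was at 1.03 there and between 6.32 and 7.79 in all others, Cbln3 at 0.61, Pcp2 at 0.52 and Neurod1 at 3.68, and Pcp4 was the only member of the list not below all other libraries. Another library, in block G, had an interferon-stimulated score of 8.12 (next 2.71), an MHC class I score of 5.44 (next 1.67) and a microglia score of 2.91 (next 1.24). Its Irf7 was at 6.47 and its Mx1 at 5.69, with at most 4.04 and 2.61 elsewhere. In brain 86 the pituitary hormone genes Gh1 (10.24, next 5.58), Pomc (6.30, next 4.58), Cga (4.37, next 3.31) and Tshb (3.10, next 1.88) were higher than in any other library, and its oxidative phosphorylation score was the lowest, −4.13. Gh1 exceeded a level of 3 in 3 libraries. The prolactin gene Prl exceeded it in 5 and was highest not in brain 86 but in brain 67 (8.05, next 8.0). A library of block D was lowest for hypothalamic neuropeptides (−4.44, next −2.15), monoamine neurons (−4.03, next −3.15) and choroid plexus (−3.08, next −2.44). Of these gaps, only that for hypothalamic neuropeptides exceeded 1 unit.

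Separate levels at gene copies may come in part from reads divided between a copy and its parent gene. Over 13 copies with a parent in the table, the median slope of the parent's per-million level on the copy's was −0.807 (95% interval −1.23 to −0.535), where −1 is a plain exchange of reads; with reassigned parents the median was 0.000733 and the lowest of 1000 was −0.0991. Plain exchange does not cover every copy: only 1 of the single intervals held −1, the parent fell by more than the copy gained for Ldhal1 (−7.63), Rps10l6 (−3.50), Prmt1l1 (−1.59) and Rpl30l2 (−1.23), the slope lay near 0 for RT1-O1l1 (−0.0525), Rpl36l6 (−0.0252) and Zfp94l1 (0.0719), and the other 6 lay between −0.913 and −0.535. An inherited variant at a single place stays open: of the 6 autosomal copies with 3 levels, Hardy-Weinberg proportions were not rejected for 4 with the middle level as heterozygote, but for 3 of these 4 they were not rejected with an outer level either, and they were rejected each way for Hbbl1 and Ndrg3-ps1, so the counts of copies do not decide. Over all 27 autosomal genes of 3 levels, copies included, these proportions were not rejected for 22 with the middle level as heterozygote. With the lowest level as heterozygote they were not rejected for 5, and with the highest for 5. Those genes include copies with their parents and near neighbours, so they are not separate counts. Genotypes are not used here.

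The count of 1370 genes that differed between identifier blocks was not reached by random assignment: 1 of 100 assignments of libraries to blocks, the real one, gave as many, the highest other gave 513, and without the 17 libraries of fewest genes the real one gave 498 and the highest other 2. A share of 1 in 100 is the smallest these assignments can give. They concern the count and do not show which of the 1370 genes differ. A cause was to leave under 50% of the genes called and its absence over 90%, bounds set beforehand for depth and cell types; 82% stayed called with ribosomal and nuclear RNA in the model (permuted values 82.9% at the lowest), 67% with library depth (87.7%), 21.9% with cell type scores (49.3%) and 31.4% with activity and stress scores (78.5%). Each of the 4 thus removed more of these calls than any of 20 permutations. Differing shares of cell types and differing activity at death, which met the first bound, are candidate explanations. Permuted cell type scores reached that bound too, at 49.3% in the lowest of 20 permutations. Differing shares of brain regions have less behind them. The olfactory bulb score differed between blocks, but cerebellar (adjusted permutation p = 0.164), striatal (0.180), cortical and hypothalamic (0.361 each), thalamic (0.434) and monoamine scores (0.629) did not pass. 2 results stand against any of the 4, as measured here, as the whole cause. In the order RNA, depth, cell types and activity, the real assignment still called 1662, 925, 487 and 479 genes. The other assignments called at most 3, 630, 32 and 23. The median variance between blocks of the 1370 genes moved from 6.63% to 6.68%, 6.31%, 5.04% and 5.63%. Members of the activity lists are themselves among the called genes, as is Cdhr1 of the olfactory bulb list (F-test adjusted p = 2.81e-06). What the blocks stand for is not given, and the design names no biological group to set beside them.

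Tph1 fell into a lower level in 58.8% of libraries (0.96 ± 0.56) and an upper level in 41.2% (4.74 ± 0.84), and pineal tissue in some of the pieces is a candidate explanation. Within the upper level the median r of 11 other pineal genes with Tph1 was 0.641, and 9 of the 11 had an adjusted permutation p under 0.05: Pde6c had r = 0.867 and rho = 0.885 (permutation p = 1e-05 for each, the smallest they can give, adjusted 2e-05 and 2.2e-05; 0.865 without 2 libraries, within 6 blocks 0.820 to 0.953). Within the lower level the median r was 0.0951, with 2 genes above 0.5 and 4 of the 11 past the threshold, and the difference between the levels was not tested. Most of the 11 genes had a mean over all libraries under the level minimum of 1, such as Crx at 0.30 and Gngt1 at 0.37. In the lower level Crx and Gngt1 were each above 0 in 46 libraries, so values near the floor limit r there. A variant at Tph1 alone is argued against by 5 pineal genes on other chromosomes with r above 0.5 in the upper level. The split argues against it too, as each of the 11 genes had a higher mean in the upper level. Lhx4 was at 1.561 ± 0.422 there and 0.889 ± 0.259 in the lower level. Gngt2 was at 1.479 ± 0.278 and 1.048 ± 0.211, and Asmt at 2.274 ± 0.271 and 1.888 ± 0.208. For Aanat (0.862 ± 0.277 and 0.809 ± 0.254), Drd4 and Pde6b the rise was within the spread. These differences of means were not tested. The 2 genes that did not pass in the upper level were Aanat, with r = 0.0773 (permutation p = 0.363, adjusted 0.421) and rho = 0.0362 (p = 0.667, adjusted 0.757), 0.0643 without 2 libraries and −0.443 to 0.780 within 6 blocks, and Pde6b, with r = 0.0669 (p = 0.430, adjusted 0.473) and rho = 0.0767 (p = 0.366, adjusted 0.473), 0.0523 without 2 libraries and −0.211 to 0.305 within 6 blocks.

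Of the 8 renamed libraries whose earlier and corrected identifiers lie in different blocks, 2 were nearest to the block of the earlier one and 6 to that of the corrected one, but the same assignment was right for 55.2% of other comparisons, so it decides nothing.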
